A study of Gallus gallus with 88 samples.

How the data were processed

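Breast muscle (Musculus pectoralis major) of broiler chickens was measured on 88 Affymetrix 1-colour arrays, 1 array per animal per the series design. Per the labels' protocols, eggs were kept at 37.8 °C apart from a treatment interval on embryonic days 7 to 10 or 10 to 13, when treated eggs were held at 38.8 °C or 36.8 °C. Total RNA of single frozen tissue samples was extracted, treated with DNase and labelled as biotinylated cRNA, per the labels' protocols. The submitters' processing notes name GCOS 1.1.1, the scanner software. The method that summarised probes to probe sets, the normalization and the annotation are not given in the sources used here.

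The deposited values are 1 number per probe set and array, read here as log2 signal because they run from 0 to the mid teens, which a linear intensity would not. The authors deposited these log2 values in a pair of tables, which differed in 0 values. Each table holds 20804 rows, of which 98 are control probe sets and 20706 were tested. The embryo arrays had a median log2 signal between 7.56 and 8.13 and the post-hatch arrays between 6.32 and 6.76, so levels were compared only within the embryo set and within the post-hatch set. The lowest deposited value is 0, held by 202 to 873 probe sets on a post-hatch array and by 40 to 148 on an embryonic day 10 array. A fold change of a gene near that floor is therefore uncertain in size. Arrays give no read depth, and the number of arrays limits the precision.

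Groups came from the labels. Each age had 8 arrays per temperature in the embryo, and post-hatch day 35 had 8 arrays for each of 4 treated groups. The 8 post-hatch controls carry the label of an interval (2 for days 7 to 10, 6 for days 10 to 13), but all were kept at 37.8 °C throughout and were used as 1 group. The labels give no sex. In the listing of samples, all 38.8 °C arrays of an age stand with 4 of its controls and all 36.8 °C arrays with the other 4 controls. These sets are called listing blocks here, and they were treated as a possible technical batch. What they stand for is not stated. Scan dates were not used here. No pair of arrays held identical values.

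Gene names came from the platform annotation, updated through Entrez identifiers to the names of assembly GRCg7b, which also gave the chromosome W and Z assignment. A single symbol was found for 12300 probe sets, several for 256 and none for 8150. The 12300 cover 11528 distinct symbols, and 11727 probe sets matched by Entrez identifier. No gene was named from a probe set with several symbols. A gene with several probe sets was represented by that with the highest mean.

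Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), 2-sided, with Benjamini-Hochberg adjustment over the 20706 probe sets of a comparison and a threshold of 0.05. Every adjusted p of a gene below is from this limma fit. Where probe sets at an unadjusted p under 0.05 are counted, a share of 0.05 is expected without any change. Against control that count was 2.36 to 6.40 percent on day 10 and at day 35, and 12.3 and 14.2 percent on day 13. A count near or under the expected share is no sign of change. All groups of an age shared 1 estimate of the spread. The change from embryonic day 10 to day 13 in controls was fitted on all 48 embryo arrays. An error given as SE is that of the log2 difference, and a mean ± SD is over 8 arrays unless stated.

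A set of 24 gene lists was fixed before the data were examined: fast-twitch and common sarcomere; slow, cardiac and embryonic sarcomere; myogenic regulation; cell cycle; extracellular matrix and fibroblast; heat shock and chaperone; glycolysis and glycogen; oxidative phosphorylation and citrate cycle; fatty acid oxidation and uptake; adipocyte markers; sterol and fatty acid synthesis; immune cell markers; erythroid markers; endothelial markers; cartilage markers; nerve and Schwann cell markers; epidermis and feather markers; protein breakdown and autophagy; growth factor and thyroid hormone signalling; hypoxia response; amino acid and unfolded protein response; immediate early genes; circadian clock; and ribosomal proteins. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists, and again with the correlation estimated and with fry. A pass in camera says that a list moved relative to the other genes. Listed names that the annotation resolved to a different gene (MBP, ALAS2, KRT15, KRT19, CCNB2 and MYH6) were left unmatched, a choice made after list results were seen.

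The named genes follow a rule fixed before the data were examined. For each comparison with control it takes up to 6 named genes with the largest rise and 6 with the largest fall past the threshold, up to 3 members of each list past it, and 2 members of a list with the smallest p as values where none passed. Where fewer than 10 probe sets passed, it takes the 10 with the smallest p. Further genes were fixed by name (CIRBP, RBM3, HSP90AA1, HSPA8, PAX7, MYOD1, MYOG, MSTN, IGF1, DIO3, MKI67, COL1A1, FABP3 and FABP4). For the other comparisons the rule takes the 6 largest rises and falls. List members are also named there, an extension made after values were seen. As run, the rule also passed over microRNA genes, which it did not say; MIR125B2, which the rule as fixed takes, is given all the same, but is not among the named genes in the counts of alternative values. Not every gene the rule takes is printed. A gene taken for its small p tends to show little overlap between groups, so a lack of overlap is no separate support.

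The developmental axis score is the mean log2 signal of the 200 probe sets with the largest rise from day 10 to day 13 minus that of the 200 with the largest fall. The probe sets were chosen in the controls of the other listing block, so that choice and test share no array. The score of 8 treated arrays was set against the 4 controls of their own block by an exact 2-sided permutation test. Effects at the end of the interval and at day 35 were correlated across probe sets, against 100 regroupings of the arrays. Effects of both temperatures share controls, so their correlation was set beside 100 simulations of unchanged groups and repeated with split controls.

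The gene tests were run on simulated data with the real means and spreads, with 50 probe sets changed by each size. At embryonic day 10, 38.8 °C against control, 34 percent of changes of 0.5 log2 were recovered, and 78 percent of changes of 1. For the same contrast on day 13 these shares were 68 and 86 percent, and for 38.8 °C on days 7 to 10 at day 35 they were 26 and 64 percent. No recovered change had the wrong sign.

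Alternatives fixed beforehand were the second table, quantile normalization, a filter on dim probe sets, a trended and robust prior, fitting only the groups compared, the listing block as a term, 1 row per gene, the mean signal of 18 chromosome W probe sets as a covariate, controls of the same interval, other sizes of the axis and the list tests above. Others were added after seeing the data: the block with the W covariate, with quantile normalization or with the level of the bioB hybridisation control (above or below 8 log2), the block in camera, own-block controls for the correlation of early and late effects, leaving out the array with the lowest correlation to its age, leaving out the array that stood far from its group for a named gene, and leaving out each treated array in turn from the axis score. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.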

Results

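Messenger RNA of broiler breast muscle was measured at the end of a transient change of incubation temperature and again at slaughter age. The embryo set held 48 arrays, 8 for each of 38.8 °C, 37.8 °C and 36.8 °C at embryonic day 10 (treated on days 7 to 10) and at embryonic day 13 (treated on days 10 to 13). The post-hatch set held 40 arrays at day 35, with 8 for each temperature and interval and 8 controls. Within an age, the median correlation of an array with the others was 0.904 to 0.955 on day 10, 0.947 to 0.963 on day 13 and 0.901 to 0.947 at day 35. Among controls alone, which share a temperature, the listing blocks differed at 1684 probe sets on day 10, 183 on day 13 and 34 at day 35. Treated minus control values are given below first over all 8 controls and then within the treated group's own block, where that ends or adds a list call or moves a named gene other than those near 0 by over 1.5 times. List results with the block were chosen after the data were seen and use camera at the preset correlation.

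Normal development from embryonic day 10 to day 13 was followed in the controls. Fast-twitch and common sarcomere genes rose as a list, with MYH1C, a fast myosin heavy chain, up by 4.52 ± 0.24 log2 (SE, n = 8 and 8, adjusted p = 1.23e-18), from 6.38 ± 0.52 to 10.90 ± 0.36. Genes of cartilage matrix fell, with COL9A1, a collagen of cartilage, from 10.02 ± 0.63 to 5.14 ± 0.72. HAPLN1 fell by 4.28 and ACAN, the large cartilage proteoglycan aggrecan, by 3.48. AQP4, a water channel, rose by 3.90 and AHSG by 3.30. Every control array of day 13 lay beyond the day 10 mean for each of these genes. Among treated arrays, COL9A1 also differed within an age. It read 3.78 on treated array 12 of day 10 and 10.24 on treated array 29 of day 13. Whether the share of cartilage tissue in the samples differed between the ages was not tested, so the fall of cartilage genes may not be a change within muscle. In all, 1999 probe sets were higher and 3553 lower on day 13.

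Grouped by list, 16 of 19 fast-twitch and common sarcomere genes rose and 1 fell, among them MYH1B, a further fast myosin heavy chain (1.87). This list passed camera at an adjusted p of 7.65e-21 and an adjusted p of 0.00596 with an estimated correlation, the only one of 57 list calls in the data to keep it. Of 18 myogenic regulation genes 13 rose and 1 fell, with CHRNG, the fetal subunit of the acetylcholine receptor, up by 1.47 and MEF2A by 0.53. That list had an adjusted p of 5.41e-07, and 0.0994 as the adjusted p with an estimated correlation. The slow, cardiac and embryonic sarcomere list was mixed: 6 of 15 rose, including MYBPC1 (1.82), and 3 fell, including MYL4, the embryonic myosin light chain (by 1.53). Its adjusted p was 0.0316, and the adjusted p was 0.581 with an estimated correlation. Of 29 cell cycle genes 19 fell and 0 rose, such as RRM2, a subunit of ribonucleotide reductase (by 0.65), and MCM3 (by 0.53). Of 14 cartilage markers 11 fell and 1 rose, and the transcription factor SOX9 fell by 2.29. Of 25 genes of fatty acid oxidation and uptake 11 rose and 0 fell, with PPARGC1A up by 1.23, PDK4 by 1.98 and FABP3, the muscle fatty acid binding protein, by 1.20. Of 9 adipocyte markers 5 rose (ADIPOQ by 1.73), and of 11 erythroid markers 4 fell. Among these the embryonic globin HBE fell by 3.25. These last lists passed camera at adjusted p of 1.62e-04 (cell cycle), 4.50e-06 (cartilage), 0.00164 (fatty acid), 0.00224 (adipocyte) and 0.0144 (erythroid). With an estimated correlation their adjusted p were 0.517, 0.408, 0.517, 0.144 and 0.517. Adjusted over the list alone, the counts were the same apart from 2 rising cell cycle genes, 7 falling erythroid markers, 8 rising slow sarcomere genes and 2 falling myogenic regulation genes. With the block the hypoxia response list passed as well, as higher (adjusted p = 0.0433). MYOG rose by 0.46, MYOD1 by 0.28, MSTN (myostatin, which limits muscle growth) by 0.81 and IGF1 by 0.79, while DIO3, which inactivates thyroid hormone, fell by 0.78 and HSPA8 by 0.30.

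**Figure D1:**
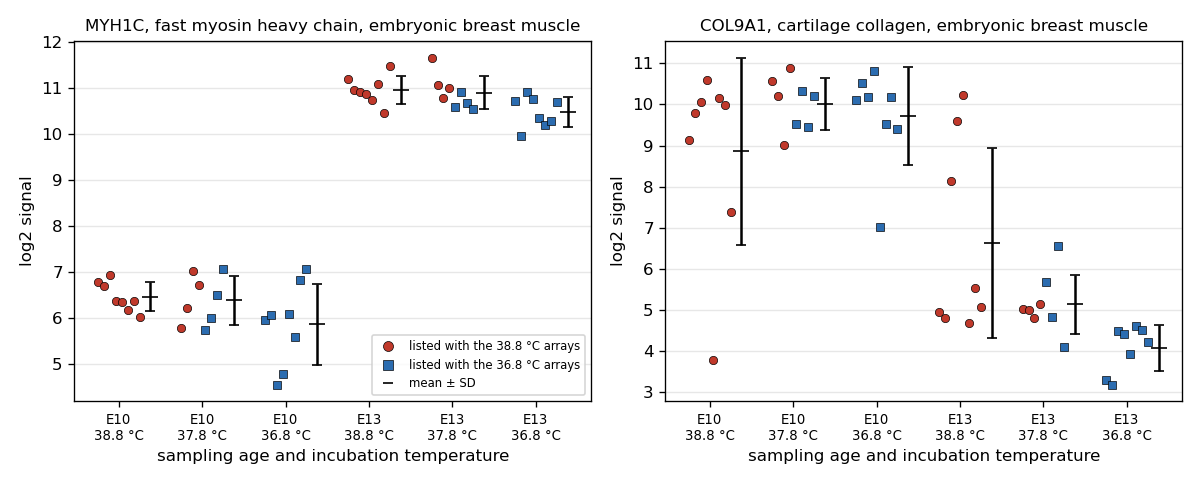
Log2 signal of MYH1C (left) and COL9A1 (right) on each embryo array, by sampling age and incubation temperature, with symbols for the listing block and the mean ± SD of 8 arrays. MYH1C rose by 4.52 from day 10 to day 13 in controls, and COL9A1 was above 8 on 3 of the 8 arrays of 38.8 °C on day 13.

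At embryonic day 10, after 38.8 °C on days 7 to 10, fatty acid oxidation and uptake genes were the list with the smallest camera p over all 8 controls. Of 25 measured, 22 were higher than in controls, at a median of 0.20 log2, with PPARGC1A, a coactivator of mitochondrial genes, at 0.62 ± 0.20 (SE) and PPARA at 1.03 ± 0.37. PPARGC1A was highest on array 9 (9.66), the array with the lowest correlation of its age (0.904), and within the listing block PPARA stood at 0.48 ± 0.42. Oxidative phosphorylation and citrate cycle genes were higher for 43 of 46 (median 0.09, with ATP5O at 0.20 ± 0.09). With 1 row per gene the median over all genes was 0.05 in this contrast, so counts of higher genes hold part of that shift. The hypoxia response list was higher for 10 of 12 genes, with VEGFA, a vascular growth factor, at 0.26 ± 0.08 and EGLN3 at 0.63 ± 0.23. Extracellular matrix and fibroblast genes were lower for 15 of 22 (TNMD -0.68 ± 0.26, or -0.40 ± 0.15 without array 12; FMOD -0.63 ± 0.25), as were cartilage markers for 12 of 14. On array 12 COL9A1 read 3.78, against 7.39 or more on the other 7 arrays. The heat shock and chaperone list, at a median of 0.03 over 23 genes, did not pass (adjusted p = 0.545), with HSPD1, the mitochondrial chaperonin, at 0.40 ± 0.14 (0.16 ± 0.15 within the block) and DNAJA1 at 0.33 ± 0.12 (0.22 ± 0.15).

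Epidermis and feather markers, of another tissue, were also higher on these arrays for 8 of 9 genes (KRT5 1.04 ± 0.51, CDH1 0.77 ± 0.30), and immediate early genes were lower for 10 of 12. Camera gave adjusted p of 7.11e-04 for fatty acid oxidation, 0.00308 for oxidative phosphorylation, 0.00985 for extracellular matrix and for cartilage markers, and 0.0149 for hypoxia response, epidermis and feather markers and immediate early genes. For each of the 7 lists the adjusted p was 0.887 with an estimated correlation. No single gene passed: limma called 0 probe sets, with 1303 at an unadjusted p under 0.05 (722 without array 9, 446 with the block as a term), and the smallest adjusted p of 0.628 held for LGI2 (-0.52 ± 0.11), TCEA2 (-0.31 ± 0.07), CTHRC1 (-0.56 ± 0.13), KLF2 (-0.39 ± 0.10), WISP1 (-0.54 ± 0.15) and BATF3 (0.64 ± 0.18). Counts adjusted over the list alone were 1 hypoxia response gene higher and 1 immediate early gene lower, against 0 over all genes. MYOD1 (-0.09 ± 0.14), MYOG (-0.16 ± 0.13), HSPA8 (0.04 ± 0.05) and the cold-inducible RBM3 (0.09 ± 0.05) did not pass, and MYOD1 and MYOG changed sign within the listing block. Within the block, the epidermis and feather markers (median 0.02, adjusted p = 0.658; KRT5 0.42 ± 0.59), hypoxia response (0.338) and immediate early genes (0.766; KLF2 -0.24 ± 0.12) no longer passed camera. Ribosomal proteins passed there as higher (adjusted p = 7.05e-04), and oxidative phosphorylation (7.58e-11) had a smaller p than fatty acid oxidation (4.35e-08).

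At embryonic day 10, after 36.8 °C on days 7 to 10, no gene passed, and no list passed over all 8 controls. Among the genes with the smallest p, RPS6KL1 was 7.66 ± 0.05 against 7.33 ± 0.14 in controls, with all 8 treated arrays above every control. That lack of overlap goes with the choice by small p and is no further support. VSIG10L was 9.10 ± 0.20 against 9.62 ± 0.28. SLC6A14, an amino acid transporter, stood at 0.69 ± 0.17 (SE), TUBA8B at -0.64 ± 0.16 and HDC, which makes histamine, at -0.35 ± 0.10. In the muscle lists, PVALB (parvalbumin) was at -0.41 ± 0.15, MYH1B at -0.37 ± 0.17 and CAPN3, a muscle calpain, at -0.61 ± 0.25. HSPA8 (-0.01 ± 0.05), RBM3 (-0.05 ± 0.05) and MYOG (-0.04 ± 0.13) lay near 0, and the sign of each flipped under quantile normalization or the block term. Limma called 0 probe sets, with 489 (2.36 percent) at an unadjusted p under 0.05 and a smallest adjusted p of 1. That percentage is under the share of 0.05 expected without any change. Within the block 6 lists passed camera: fast-twitch and common sarcomere (adjusted p = 0.00209), myogenic regulation (0.00213), erythroid markers (0.00816), immediate early genes (0.0143) and ribosomal proteins (0.0190) as lower, and epidermis and feather markers, of another tissue, as higher (median 0.73, 0.00213). HDC stood there at -0.18 ± 0.10 and MYOG at -0.20 ± 0.16. Without array 61, and without the block term, MYOG was at -0.11 ± 0.13.

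At embryonic day 13, after 38.8 °C on days 10 to 13, cartilage and connective tissue genes were higher. Of 14 cartilage markers 13 were higher, at a median of 0.53 log2, with LECT1 (chondromodulin) at 0.18 ± 0.05 (SE) and CHAD at 0.48 ± 0.19. All 22 extracellular matrix and fibroblast genes were higher (median 0.11), with OGN at 0.24 ± 0.08 and PDGFRA at 0.18 ± 0.06. The collagen chaperone SERPINH1 was at 0.22 ± 0.05. With 1 row per gene the median over all genes was 0.06 in this contrast, so counts of higher genes hold part of that shift. The cartilage signal was uneven: COL9A1 read 8.15 to 10.24 on 3 of the 8 arrays and at most 5.53 on the others, while the highest control was 6.56. A single probe set rose, annotated to the microRNA gene MIR125B2, by 0.69 ± 0.11 (adjusted p = 0.0292); all 8 treated arrays were above every control.

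Sterol and fatty acid synthesis genes were lower for 15 of 18, and ribosomal proteins went both ways (21 of 43 higher). Camera gave adjusted p of 7.58e-04 for cartilage markers, 0.00445 for extracellular matrix, 0.0223 for sterol synthesis and 0.0299 for ribosomal proteins, and for all 4 the adjusted p was 0.874 with an estimated correlation. With p adjusted over the list alone, 1 cartilage, 1 immune cell, 1 immediate early and 1 clock gene were higher, against 0 over all genes. Genes with the next smallest p did not pass: ACE at 0.76 ± 0.14, EFEMP1 at 0.28 ± 0.05, KCNA1 (a potassium channel) at -0.42 ± 0.08, MLIP at 0.45 ± 0.09, LBFABP, a liver fatty acid binding protein, at 0.77 ± 0.16 and HAS3 at -0.54 ± 0.12, with adjusted p of 0.136 to 0.157. CD74, a marker of immune cells, was at 0.39 ± 0.09, the small heat shock protein HSPB7 at -0.28 ± 0.09, HSPA8 at 0.02 ± 0.04, RBM3 at 0.05 ± 0.04 and MYOG at -0.06 ± 0.07. The sign of HSPA8 flipped under quantile normalization. The heat shock and chaperone list did not pass (adjusted p = 0.259). Limma called 1 probe set higher and 0 lower, with 2557 at an unadjusted p under 0.05. Against the own-block controls MIR125B2 stood at 0.52 ± 0.12 (adjusted p = 0.694), PDGFRA at 0.08 ± 0.07, HAS3 at -0.35 ± 0.13 and HSPB7 at -0.13 ± 0.10; sterol and fatty acid synthesis no longer passed (0.218), while oxidative phosphorylation passed as lower (0.00910) and immune cell markers as higher (0.0328). No probe set was called without the dim ones or with only the 2 groups fitted, and 2 were after quantile normalization or with a trended and robust prior.

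At embryonic day 13, after 36.8 °C on days 10 to 13, MCOLN1, a lysosomal cation channel, rose by 0.25 ± 0.04 log2 (SE; adjusted p = 0.0271), from 10.28 ± 0.07 to 10.53 ± 0.06, with all 8 treated arrays above every control. Over the alternatives the adjusted p of MCOLN1 ran from 0.00732 to 0.187. The call was lost with only the 2 groups fitted (0.187), with block and quantile normalization (0.123) and with block and bioB (0.101). In these 3 fits the difference stood at 0.25, 0.17 and 0.26 log2. Energy and protein synthesis lists were higher over all 8 controls. Neither passed with an estimated correlation, and ribosomal proteins did not pass within the block. Oxidative phosphorylation and citrate cycle genes were higher for 39 of 46 (median 0.08), with COX6C at 0.20 ± 0.06 and PDHB at 0.17 ± 0.05. Ribosomal proteins were higher for 39 of 43 (median 0.07), with RPS13 at 0.19 ± 0.05. Sterol and fatty acid synthesis genes were higher for 13 of 18, with SREBF2, the regulator of sterol synthesis genes, at 0.28 ± 0.08 and FDFT1 at 0.31 ± 0.10. Protein breakdown and autophagy genes were higher for 15 of 19. The median over all genes, with 1 row per gene, was 0.03 in this contrast. Extracellular matrix and fibroblast genes were lower for 18 of 22 and circadian clock genes for 7 of 9.

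Camera gave adjusted p of 0.00576 for oxidative phosphorylation, 0.00671 for ribosomal proteins, 0.0150 for extracellular matrix and 0.0319 for the other 3 lists. For all 6 the adjusted p was 0.950 with an estimated correlation. Higher members adjusted over the list alone were 3 of sterol and fatty acid synthesis and 1 each of protein breakdown, ribosomal proteins, fatty acid oxidation and endothelial markers, against 0 over all genes. MAB21L1 (0.38 ± 0.07), AKR1D1 (0.54 ± 0.10, a steroid reductase), MRPL3 (0.23 ± 0.04, of the mitochondrial ribosome), LGI2 (0.64 ± 0.12), ST8SIA2 (0.43 ± 0.09) and WLS (0.38 ± 0.08) had adjusted p of 0.0611 to 0.0626, and HADHB stood at 0.21 ± 0.05. MKI67 (-0.33 ± 0.11), PAX7 (0.14 ± 0.05), HSPA8 (0.09 ± 0.04) and RBM3 (-0.04 ± 0.04, reversed within the block) did not pass. Limma called 1 probe set, with 2932 at an unadjusted p under 0.05. The count was 0 with only the 2 groups fitted, 11 with 1 probe set per gene, 22 after quantile normalization, 76 with a trended and robust prior and 128 without dim probe sets. Against the 4 own-block controls, 798 probe sets were higher and 77 lower, and 5 higher and 2 lower after quantile normalization. The median over all probe sets was 0.09 in this contrast and 0.00206 after quantile normalization. The low arrays differed from those 4 controls by a median of 0.32 over these probe sets and from the other 4 controls by 0.09 in the same direction. All 4 own-block controls, and 4 of the 8 treated arrays, had a bioB hybridisation control above 8 log2, as no other control of this age did. Within the block, extracellular matrix and fibroblast (adjusted p = 0.137), sterol and fatty acid synthesis (0.645), circadian clock (0.691) and ribosomal proteins (0.137) no longer passed camera. PDHB stood there at 0.26 ± 0.06 and passed limma (adjusted p = 0.0279), and MKI67 stood at -0.15 ± 0.12. MAB21L1, AKR1D1, MRPL3, LGI2, ST8SIA2 and WLS also passed limma there as higher, at adjusted p from 0.0153 (AKR1D1) to 0.0373 (WLS).

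The temperatures were also set against each other at each embryonic age. On day 10, VSIG10L rose by 0.74 ± 0.11 log2 (SE) and HDC by 0.55 ± 0.10 at 38.8 °C relative to 36.8 °C. LGI2 fell by 0.65, TCEA2 by 0.50, RPS6KL1 by 0.43, RFC4 (a clamp loader of DNA replication) by 0.39 and DNM1 by 0.39, with adjusted p of 0.00395 to 0.0417. All 8 arrays of 38.8 °C lay beyond the 36.8 °C mean for each of these 7 genes. The fatty acid oxidation and uptake list (21 of 25 higher) and the hypoxia response list (11 of 12 higher) passed camera at an adjusted p of 0.0493. For both the adjusted p was 0.993 with an estimated correlation. Adjusted over the list alone, 5 fatty acid and 6 hypoxia response genes were higher, against 0 over all genes. Limma called these 7 probe sets and 5048 at an unadjusted p under 0.05. Each temperature lies in its own listing block: with the block as a term 0 passed (652 unadjusted) and SEs were larger. VSIG10L then stood at 0.79 ± 0.19, LGI2 at -0.57 ± 0.20 and RPS6KL1 at -0.34 ± 0.13, while HDC stood at 0.21 ± 0.14, TCEA2 at -0.33 ± 0.11, RFC4 at -0.25 ± 0.12 and DNM1 at -0.25 ± 0.12. The hypoxia response list no longer passed camera (adjusted p = 0.570). Oxidative phosphorylation (8.77e-06), ribosomal proteins (1.22e-04), fast-twitch sarcomere (0.0209), myogenic regulation (0.0290) and glycolysis and glycogen (0.0392) then passed as higher and extracellular matrix (0.0290) as lower. Without array 9 of 38.8 °C, or with only the 2 groups fitted, 2 probe sets passed; 11 did with a trended and robust prior and 13 without dim probe sets. Quantile normalization moved the median of all genes from 0.05 to -0.07 and called 330.

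On day 13, single genes of cartilage and connective tissue were among those that rose at 38.8 °C relative to 36.8 °C. COL9A1 was 6.63 ± 2.32 against 4.08 ± 0.56 (2.55 ± 0.69 SE, adjusted p = 0.0306), with 3 of the 8 arrays at 8.15 to 10.24 and the others at most 5.53. GDF5, a growth factor of joints and cartilage, rose by 1.18, the matrix-associated CCN3 by 1.43, ITGBL1 by 1.37 and the collagen COL8A1 by 1.27. LBFABP rose by 1.42 ± 0.16 (adjusted p = 9.94e-05). CX3CR1, a chemokine receptor of myeloid cells, fell by 1.09, LGI2 by 1.07, AKR1D1 by 0.75, PRLHR2 by 0.73, TMEM244 by 0.67 and the metalloproteinase MMP27 by 0.64. The proliferation marker MKI67 rose by 0.49. In all 733 probe sets were higher and 484 lower, with a median absolute difference of 0.31 log2 and 13 beyond 2-fold. With the block as a term 1 was higher and 27 lower, and the median over all probe sets was -0.09.

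By list, 3 of 22 extracellular matrix and fibroblast genes rose (OGN by 0.41) with 20 of 22 higher, and 1 of 14 cartilage markers rose with 13 higher. Of 46 oxidative phosphorylation and citrate cycle genes 6 fell (COX6C by 0.28), of 43 ribosomal proteins 4 fell, and of 18 sterol and fatty acid synthesis genes 3 fell (FDFT1 by 0.43, SREBF2 by 0.34). Of 9 circadian clock genes 2 rose (CLOCK by 0.38; not called without array 79 of 36.8 °C, at 0.30 ± 0.10 and adjusted p = 0.108). Adjusted over the list alone, 12 extracellular matrix, 4 cartilage and 4 clock genes rose, and 7 oxidative phosphorylation, 4 ribosomal and 9 sterol synthesis genes fell. Camera adjusted p were 9.65e-06 for extracellular matrix, 1.32e-04 for cartilage markers, 8.30e-05 for sterol synthesis and 6.25e-04 for the clock; with an estimated correlation the adjusted p was 0.551 for these 4 and 0.724 for oxidative phosphorylation and ribosomal proteins. The cartilage list mean was 8.03 ± 0.89 at 38.8 °C, 7.43 ± 0.20 in controls and 7.31 ± 0.11 at 36.8 °C. The control blocks differed in the called direction by a median of 0.15 over the 1217 probe sets. Of the 28 probe sets called with the block as a term 17 were among the 1217, including LGI2 (-1.17 ± 0.22) and AKR1D1 (-0.96 ± 0.17). COL9A1 stood at 2.84 ± 1.22, GDF5 at 1.81 ± 0.55, CX3CR1 at -1.28 ± 0.39 and MMP27 at -0.85 ± 0.26, LBFABP at 0.94 ± 0.26, MKI67 at 0.14 ± 0.17, and CLOCK changed sign (-0.04). Sterol and fatty acid synthesis (adjusted p = 0.311) and the clock (0.570) no longer passed camera, while endothelial markers (0.0475) and protein breakdown and autophagy (0.0389) passed as lower. Quantile normalization called 1118 higher and 1138 lower.

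The position of treated embryos between the day 10 and day 13 controls was measured as a score. At 38.8 °C on day 10 the score was higher than in own-block controls by 0.37, or 12.5 percent of the distance between the ages (exact permutation test over 495 splits, p = 0.172, 8 against 4 arrays, adjusted over 4 tests 0.453), and by 0.24 without array 12, on which COL9A1 was low. At 38.8 °C on day 13 the difference was -0.02 (exact p = 0.895), and it ran from -0.08 to 0.08 as each treated array was left out. The 3 arrays of high COL9A1 had the lowest scores (1.52, 1.28 and 0.89, against 1.54 or more in the own-block controls). The score subtracts genes with the largest falls from day 10 to day 13, and cartilage genes had such falls. A high COL9A1 therefore goes with a lower score partly by definition. The score may thus partly follow the share of cartilage tissue in a sample, which was not measured. At 36.8 °C it was -0.21 on day 10 (exact p = 0.410) and -0.17 on day 13 (exact p = 0.226). None passed, and the smallest p these splits allow is 0.00202.

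**Figure D2:**
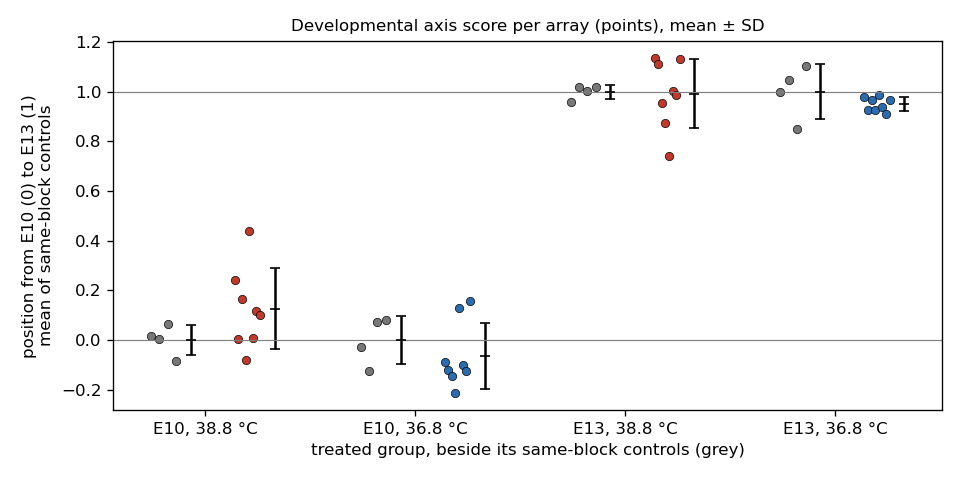
Developmental axis score of each treated embryo array and its own-block controls, scaled so that the own-block day 10 control mean is 0 and the day 13 mean is 1, with mean ± SD. The largest mean displacement, 12.5 percent at 38.8 °C on day 10, did not pass the permutation test of the means (exact p = 0.172).

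At day 35, after 38.8 °C on days 7 to 10, energy and vessel genes were higher as lists over all 8 controls. Neither list passed with an estimated correlation, and the energy list did not pass within the block. Of 46 oxidative phosphorylation and citrate cycle genes 38 were higher (median 0.08; ATP5J 0.32 ± 0.13 SE), and of 12 endothelial markers 10 (median 0.20; SOX7 0.33 ± 0.13, EGFL7 0.21 ± 0.09). Ribosomal proteins were higher for 31 of 43. RHOBTB1 was 4.19 ± 0.43 against 5.12 ± 0.36, with all 8 arrays below every control (adjusted p = 0.106). ANKRD1, a stretch-responsive muscle protein, stood at -0.96 ± 0.28 and MYL2, a slow and cardiac myosin light chain, at -0.85 ± 0.40, or -0.30 ± 0.23 without array 11, which read 0. Genes expressed mainly in liver were among the smallest p, such as KLKB1 (-1.28 ± 0.32) and AMBP (-3.52 ± 0.92), beside SALL1 (-2.21 ± 0.56) and BG8, a butyrophilin-like gene (-2.09 ± 0.54). AMBP moved with the listing block: it was 7.57 ± 1.77 in the 4 controls listed with 36.8 °C and 1.90 ± 0.80 in the 4 listed with 38.8 °C. KLKB1 changed little within the block, at -1.13 ± 0.39.

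Camera gave adjusted p of 2.48e-05 for oxidative phosphorylation, 1.45e-04 for endothelial markers and 0.00500 for ribosomal proteins. With an estimated correlation the adjusted p were 0.862, 0.413 and 0.959. No member of these lists passed over all genes or adjusted over the list alone, a count of 0 in each. Against only the 2 controls labelled for the same interval ATP5J changed sign (-0.03). Limma called 0 probe sets, with 1326 at an unadjusted p under 0.05. Within the block the oxidative phosphorylation and citrate cycle list no longer passed (adjusted p = 0.627; ATP5J 0.16 ± 0.16), AMBP stood at -0.68 ± 0.79 and ANKRD1 at -0.62 ± 0.34.

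At day 35, after 36.8 °C on days 7 to 10, oxidative phosphorylation and citrate cycle genes were lower for 41 of 46 (median -0.11; ATP5O -0.30 ± 0.12 SE, NDUFS1 -0.23 ± 0.11). Extracellular matrix and fibroblast genes were lower for 20 of 22 and cell cycle genes for 23 of 29. Immune cell markers were higher for 16 of 18 (JCHAIN, of secreted antibodies, 0.80 ± 0.41) and erythroid markers for 10 of 11. Liver transcripts differed within the pooled controls: the mean of 27 liver markers was 7.45 ± 0.99 over the 16 arrays of 36.8 °C, 7.64 ± 1.49 in the 4 controls of their block and 4.03 ± 0.23 in the other 4. PCCB, a mitochondrial carboxylase subunit, was 9.24 ± 0.18 against 9.66 ± 0.14. NELL1 stood at 0.71 ± 0.19, with all 8 arrays above every control, CACNA1H at -0.63 ± 0.17 and GSTZ1 at -1.02 ± 0.29. Camera gave adjusted p of 2.64e-06 for oxidative phosphorylation, 0.0398 for cell cycle and extracellular matrix, 0.0221 for immune cell markers and 0.0308 for erythroid markers. For all 5 the adjusted p was 0.934 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Limma called 0 probe sets, with 640 (3.09 percent) at an unadjusted p under 0.05, fewer than expected without any change. Against the 2 controls labelled for the same interval, which are both listed with 38.8 °C, 42 passed. Within the block oxidative phosphorylation and citrate cycle (adjusted p = 0.774) and erythroid markers (0.0847) no longer passed, and immune cell markers turned to lower (0.508). ATP5O stood there at -0.17 ± 0.14, NDUFS1 at -0.13 ± 0.13 and JCHAIN at 0.24 ± 0.48, and sterol and fatty acid synthesis passed as lower (0.00672).

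At day 35, after 38.8 °C on days 10 to 13, immediate early genes were lower for 11 of 12 (median -0.18), with KLF2 at -0.50 ± 0.16 (SE) and NR4A3 at 7.93 ± 0.69 against 8.92 ± 0.52 in controls. ACOT11, a thioesterase, was 7.87 ± 0.30 against 8.51 ± 0.23, with all 8 arrays below every control. XDH, which makes uric acid, stood at -2.15 ± 0.63, the liver transporter SLCO1B3 at -2.27 ± 0.68 and SULT6B1L at -3.81 ± 0.94. SULT6B1L was 7.10 ± 2.01 in the 4 controls listed with 36.8 °C and 0.99 ± 1.11 in the other 4, and within the block it stood at -0.76 ± 0.76, XDH at -0.89 ± 0.69, SLCO1B3 at -0.96 ± 0.75 and KLF2 at -0.25 ± 0.19. The immediate early genes passed camera (adjusted p = 0.0120), with an adjusted p of 0.976 with an estimated correlation and 0.119 within the block, where oxidative phosphorylation passed as lower (0.0351). No member passed over all genes or adjusted over the list alone. Limma called 0 probe sets, with 651 (3.14 percent) at an unadjusted p under 0.05, fewer than expected without any change.

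At day 35, after 36.8 °C on days 10 to 13, ribosomal proteins were higher for 42 of 43 (median 0.13; RPLP1 0.26 ± 0.11 SE) and oxidative phosphorylation and citrate cycle genes lower for 39 of 46 (median -0.14; SDHA -0.49 ± 0.13, DLD -0.41 ± 0.13). Immune cell markers were higher for 17 of 18 (JCHAIN 1.44 ± 0.41), and myogenic regulation genes for 11 of 18, with CHRNG, the fetal acetylcholine receptor subunit, at 1.33 ± 0.37. The liver marker mean was 7.45 ± 0.99 over all 16 arrays of 36.8 °C, 7.64 ± 1.49 in the 4 controls of their block and 4.03 ± 0.23 in the 4 controls listed with 38.8 °C. TNNI1, a slow troponin, stood at 0.77 ± 0.27, MYH15 at 1.03 ± 0.48 and FABP3 at 0.61 ± 0.23. PITPNM3 was 8.74 ± 0.24 against 9.32 ± 0.21, MYO7B stood at 0.94 ± 0.22, with all 8 arrays above every control, and TNIP1 at 0.36 ± 0.09. Camera gave adjusted p of 4.05e-09 for ribosomal proteins, 2.31e-09 for oxidative phosphorylation, 2.84e-04 for immune cell markers and 0.0344 for myogenic regulation. For all 4 the adjusted p was 0.830 with an estimated correlation. By p adjusted over the list alone, 1 myogenic regulation gene and 1 immune cell marker were higher and 1 oxidative phosphorylation gene lower, against 0 over all genes. Limma called 0 probe sets, with 1320 at an unadjusted p under 0.05 and a smallest adjusted p of 0.321. Within the block myogenic regulation (adjusted p = 0.403; CHRNG 0.83 ± 0.43) and immune cell markers (0.997; JCHAIN 0.89 ± 0.48) no longer passed camera, and FABP3 stood at 0.37 ± 0.28. Cell cycle (8.82e-04), extracellular matrix (0.0130) and sterol and fatty acid synthesis (0.00389) passed there as lower.

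Between the temperatures at day 35, genes of liver secretion stood out. After days 7 to 10, FGG (a fibrinogen chain) fell by 6.59 log2 at 38.8 °C relative to 36.8 °C, ALB (albumin) by 6.53, SULT6B1L fell by 6.20, APOB by 6.00, AMBP by 5.97 and FGA by 5.75. After days 10 to 13, SULT6B1L fell by 6.77, FGG by 6.43, FGB fell by 6.19, ALB fell by 5.91, the defensin AvBD9 fell by 5.61 and APOB fell by 5.59. ALB was 11.79 ± 1.23 after 36.8 °C on days 7 to 10 and 5.26 ± 2.22 after 38.8 °C. The controls split the same way: ALB was 12.06 ± 1.09 (SD, n = 4) in those listed with 36.8 °C and 5.23 ± 0.90 in those listed with 38.8 °C. Outside liver genes, TSNARE1 rose by 0.64 after days 7 to 10, and AKAP6 by 0.63, NUDCD1 by 0.59, TMEM237 by 0.57 and ATP5O, of ATP synthase, by 0.52 after days 10 to 13.

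Limma called 1 probe set higher and 60 lower for days 7 to 10 and 5 higher and 48 lower for days 10 to 13. Of the lower ones 34 were shared, where independent lists would share 0.139. Oxidative phosphorylation and citrate cycle genes were higher at 38.8 °C for 41 of 46 and 39 of 46 (adjusted p = 3.39e-12 and 7.74e-09), immune cell markers were lower for 16 and 18 of 18 (0.00773 and 1.64e-07), endothelial markers were higher for 11 of 12 after days 7 to 10 (0.00126) and ribosomal proteins lower for 38 of 43 after days 10 to 13 (1.28e-04). With an estimated correlation the adjusted p were 0.561 and 0.875 for oxidative phosphorylation, 0.958 and 0.875 for immune cell markers, 0.561 for endothelial markers and 0.917 for ribosomal proteins. By p adjusted over the list alone, 7 oxidative phosphorylation genes rose after days 7 to 10 and 1 after days 10 to 13, against 0 and 1 over all genes. With the block as a term 0 probe sets passed in either interval (749 and 654 unadjusted), the FGG and ALB differences became 0.79 ± 1.28 and 0.31 ± 1.11 after days 7 to 10, and TMEM237 stood at 0.37 ± 0.23 and ATP5O at 0.27 ± 0.20 after days 10 to 13. Immune cell markers turned to higher (adjusted p = 0.0477 and 0.609), and cell cycle (6.49e-04 and 1.46e-04), heat shock and chaperone after days 7 to 10 (0.0477) and extracellular matrix after days 10 to 13 (0.0469) passed as higher. Oxidative phosphorylation (0.38 and 0.968) and, after days 10 to 13, ribosomal proteins (0.0816) then no longer passed camera. Quantile normalization called 9 higher and 36 lower for days 7 to 10, and 26 higher and 62 lower for days 10 to 13. Without dim probe sets 23 and 28 were called, without array 11 38 after days 7 to 10, and with only the 2 groups fitted 88 after days 10 to 13.

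**Figure D3:**
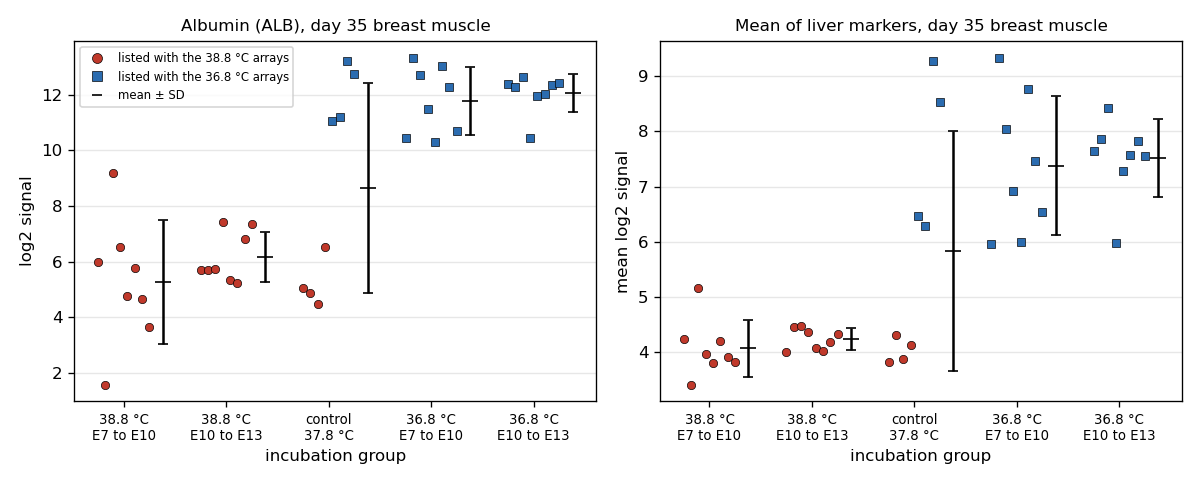
Log2 signal of albumin (left) and mean log2 signal of 27 liver markers (right) on each day 35 array, by incubation group, with symbols for the listing block and the mean ± SD of 8 arrays. The lowest albumin of the 20 arrays listed with 36.8 °C was 10.29, and the highest of the other 20 was 9.18; the controls divide by block.

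The intervals were compared at the same temperature at day 35. BG8 fell by 3.13 ± 0.54 log2 (SE) after 38.8 °C on days 7 to 10 relative to days 10 to 13 (1.17 ± 1.41 against 4.30 ± 0.81, adjusted p = 0.0205), 1 of 1 probe set called. The mean of 1.17 lies near the floor of 0, so the size of the fall is uncertain. The call was lost without array 11 of the earlier group, without dim probe sets and with only the 2 groups fitted. Oxidative phosphorylation and citrate cycle genes were higher for 38 of 46, endothelial markers for 8 of 12 and immediate early genes for 10 of 12 (camera adjusted p = 2.21e-04, 0.0217 and 0.0282), and for all 3 the adjusted p was 0.964 with an estimated correlation. After 36.8 °C, ribosomal proteins were lower for 41 of 43 and myogenic regulation genes for 14 of 18 in the earlier interval (3.98e-12 and 0.00357). For both the adjusted p was 0.778 with an estimated correlation. Limma called 0 probe sets for 36.8 °C, with 417 (2.01 percent) at an unadjusted p under 0.05, fewer than expected without any change. No member of these lists passed over all genes or adjusted over the list alone, a count of 0 in each.

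Lists that passed camera in none of the 15 comparisons without the block were heat shock and chaperone (lowest adjusted p 0.236), glycolysis and glycogen (0.101), nerve and Schwann cell markers (0.136), growth factor and thyroid hormone signalling (0.0708) and amino acid and unfolded protein response (0.224). With the block the glycolysis list passed in 1 comparison (adjusted p = 0.0392) and the heat shock list in 1 (0.0477), both given above. Among their members, between the temperatures on day 13, 5 heat shock and chaperone genes were higher and 1 lower over all genes. Adjusted over the list alone, 7 were higher and 1 lower. With 1 row per gene, 786 of all 11528 genes were called higher in this contrast and 450 lower. The temperatures lie in different listing blocks, and with the block as a term only 1 probe set of all those tested was higher and 27 lower.

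Whether an effect at the end of the interval was seen again at day 35 was asked across 20706 probe sets, which are not independent replicates. Pearson's r was -0.08 for 38.8 °C on days 7 to 10, 0.02 for 36.8 °C, and 0.02 for each temperature on days 10 to 13, with Spearman's rho of 0.06, 0.12, 0.01 and 0.02. Of 100 regroupings, 56, 88, 75 and 86 gave an r as far from 0. No overlap of calls could be asked, since limma called 0 probe sets at day 35 in these comparisons. The effects of both temperatures against the same controls correlated at -0.12 on day 10, 0.26 on day 13 and 0.11 and 0.15 at day 35, where unchanged groups sharing controls gave 0.50. The simulation holds no listing block, and the temperatures lie in opposite blocks. The covariances were -0.007, 0.011, 0.009 and 0.013, against 0.033, 0.023, 0.046 and 0.044 simulated. With each temperature set against the controls of its own block r was -0.11, -0.07, -0.07 and -0.01.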

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

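The tests on liver markers, on the listing block and temperature behind the embryonic day 13 calls, on the median difference with a cartilage covariate and on quantile normalization of the day 13 low arrays were chosen after the result was seen; the splits of the arrays, the count of calls with a cartilage covariate and the bioB test were written first.

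Liver transcripts at day 35 followed the listing block. Of 30 liver markers that had not been looked at, 21 were measured, and their median difference between controls listed with 36.8 °C and with 38.8 °C was 3.55 log2 (16 higher by over 1; exact permutation p = 0.0286 for their mean, the smallest of 70 splits of 4 against 4). The 16 arrays of 36.8 °C differed from the 4 controls of their block by -0.19 ± 0.79 (SE) in the mean of 27 markers (exact permutation p = 0.754), against a gap of 3.29 between temperatures, which argues against incubation temperature as the source. Liver RNA, or something else carried by the block, may account for it. Only 1 of the 27 markers exceeded the median probe set in controls listed with 38.8 °C, and how liver RNA would have entered stays open.

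The 1217 probe sets called between 38.8 °C and 36.8 °C on embryonic day 13 have an open origin. Over them the control blocks differed by 0.15 log2 in the called direction (highest other split 0.12), about halfway to the treated difference of 0.31, so the block may contribute and cannot be told apart from temperature as the whole source. The control blocks had the called sign for 72.7 percent of them, a share that 9 of 35 splits of the controls reached, the real one counted. Over all probe sets, the temperature difference correlated with the control block difference, which shares no array with it, at r = 0.274. No other of the 35 splits reached that, though the next gave 0.271. The block split was also the largest on day 10 (0.656, next 0.574) and at day 35 (0.416, next 0.396, after days 7 to 10, and 0.465, next 0.352, after days 10 to 13). With the block as a term the median was 0.18 with a median SE of 0.13, against 0.31 with 0.08 before. That fit subtracts the same control block difference, so it is no separate evidence, and the 0.31 is over probe sets called on it. The 17 calls left reflect a median both smaller and less precise, which leaves temperature open. Cartilage tissue on some 38.8 °C arrays was tested in 2 ways: 467 of the 1217 stayed called with the cartilage list mean as a covariate, between the bounds set beforehand, so that test decided nothing, whereas the median difference, a criterion adopted afterwards in its place, stayed at 0.31 with a median SE of 0.09. The second result argues against cartilage as the source of the median difference, not of the cartilage genes themselves.

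The 875 probe sets called between 36.8 °C and own-block controls on embryonic day 13 were weighed last. The 4 treated arrays that share the controls' bioB level were shifted by a median of 0.30 log2 and the other 4 by 0.34. By the bound written first this would count against a batch marked by bioB. However, the probe sets were called on these same arrays, and both shifts are taken from the same 4 controls, which favours similar shifts. The test therefore cannot decide whether such a batch is the source. With a bioB term the median was 0.30 (SE 0.09), and 0 passed. After quantile normalization the median shift was 0.23 with a median SE of 0.07, against 0.32 ± 0.08 before, and 7 probe sets passed, so a shift of whole arrays may account for part and the rest cannot be told apart from it. The treated arrays stood 0.09 from the other 4 controls over the same probe sets, a value with no test of its own. The low temperature stays open as an untested biological source.

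Other splits of the same arrays, 100 for each comparison with the real one counted, say whether chance can be excluded. It can for 38.8 °C against 36.8 °C on day 10 (7 called, highest other 3, 1 split as large), on day 13 (1217, highest other 1, 1 split), at day 35 (61 and 53, highest other 1 and 2, 1 split each) and for development (5552, highest other 2289, 1 split). Between the temperatures the real split is also the split by listing block. The splits there exclude chance alone and cannot tell temperature from the block. For the single calls on day 13, 3 splits gave as many for each temperature, with highest others of 1438 for 38.8 °C and 2 for 36.8 °C. That is under the share of 0.05 set beforehand, but it is not adjusted over the 15 comparisons, so chance is not excluded. These splits do not keep the listing block, within which MIR125B2 had an adjusted p of 0.694, and by probe sets at an unadjusted p under 0.05, 4 and 6 splits gave as many. Chance was not excluded for the BG8 contrast (1 called, 10 splits as large, highest other 40). All 100 splits gave at least the 0 calls of the other comparisons, with highest others of 17 and 4180 on day 10 (38.8 °C and 36.8 °C) and 3, 23, 4 and 614 at day 35 (38.8 °C and 36.8 °C on days 7 to 10, then on days 10 to 13) and 2 between the 36.8 °C intervals. The splits with 1438, 4180, 614, 23, 17 and 40 calls, several times the real counts, may point to a structure of the arrays other than the groups compared; what those splits share was not tested. A split of unequal ages carries the change of development itself, so the 2289 says nothing of another structure.

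Single arrays stood far from the rest of their group for 30 of 358 sets of values tested; chance flags about 1 in 20 groups, here 17.9. On day 10, control 63 was lowest in C17orf58 (7.41), HSPD1 (9.97), PVALB (7.05), its median signal (7.56) and its correlation to the age (0.929). Array 9 of 38.8 °C was highest in PPARGC1A (9.66) and lowest in that correlation (0.904), array 12 of 38.8 °C was lowest in TNMD (7.67), and array 61 of 36.8 °C highest in MYOG (9.23). On day 13, control 39 was highest in MYH1C (11.67), control 40 in RBM3 (12.69) and array 27 of 38.8 °C in PDGFRA (11.12), while control 91 was lowest in AKR1D1 (8.35), array 75 of 36.8 °C in HADHB (10.78) and array 79 in CLOCK (7.31). At day 35, after 38.8 °C, array 13 was highest in AMBP (5.15) and SULT6B1L (3.92), array 43 in FGB (3.88), and array 11 read 0 for MYL2 and had the lowest correlation (0.901). After 36.8 °C on days 10 to 13, array L13_161 was lowest in SULT6B1L (4.90), FGG (5.99), FGB (6.17), ALB (10.45) and APOB (4.68), array 6 was highest in SDHA (10.01), and array L13_122 was highest in FABP3 (12.47) and in median signal (6.76) and lowest in correlation (0.923). Control 81 was highest in SALL1 (5.37).

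BG8 differed between the intervals of 38.8 °C at day 35 by -3.13 log2. A difference of the effects between embryonic ages was tested and called 0 probe sets by limma for 38.8 °C (803 unadjusted) and for 36.8 °C (610 unadjusted). Both unadjusted counts are lower than expected without any change. In data outside the gene tests, the bioB hybridisation control of the day 13 controls listed with 36.8 °C was higher by 2.16 log2 than in those listed with 38.8 °C.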

How the results depend on the processing

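The list tests with the block, the block combined with the W covariate, quantile normalization or bioB, own-block controls for early and late effects, and leaving out arrays were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. The second deposited table gave the same values. Of 1988 alternative values of named genes, 1754 kept direction and side of the threshold, 147 lost the call, 38 gained one and 49 changed sign. Of the 1754, 175 come from the second table and could not differ. Only 77 of the 175 named results were called to begin with, so many values kept their side by staying uncalled. With the block alone as a term, 30 lost the call and 14 changed sign. A gene near the floor of 0 has too little signal over background to size a fold change. Unless stated, the cause was not tested.

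Quantile normalization called 2 and 22 probe sets for 38.8 °C and 36.8 °C against control on day 13 (1 each as deposited; for 38.8 °C 1 higher and 1 lower), 330 (7) and 2256 (1217, of which 1194 shared) between temperatures on days 10 and 13, and 88 (53) between temperatures at day 35 after days 10 to 13. Without dim probe sets, so with fewer tested, the counts were 0 and 128 on day 13, 13 between temperatures on day 10, 23 and 28 between temperatures at day 35 and 0 between the 38.8 °C intervals. A trended and robust prior gave 2 and 76 on day 13 and 11 between temperatures on day 10. With only the groups compared, so fewer arrays, the counts were 0 and 0 on day 13, 2 between temperatures on day 10, 88 at day 35 after days 10 to 13 and 0 between the 38.8 °C intervals. With 1 row per gene 11 passed for 36.8 °C on day 13, and with same-interval controls, both in the other listing block, 42 for 36.8 °C on days 7 to 10 at day 35 (0 with the block as a term). Without array 9 (day 10) or 11 (day 35), 2 passed between temperatures on day 10, 38 at day 35 after days 7 to 10 and 0 between the 38.8 °C intervals.

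With the block, the counts were 0 and 875 against control on day 13, 0 and 28 between temperatures on days 10 and 13, and 0 and 0 at day 35. With the block and W they were 0, 806, 0, 29, 0 and 0. With the block and quantile normalization they were 0, 7, 0, 1, 0 and 0, and 1 for 36.8 °C on days 7 to 10 at day 35. With the block and bioB, in embryos, they were 0, 0, 0 and 2. Gene lists passing with an estimated correlation were 0 in each comparison that had any, and 1 of 8 in development. By fry they were 0 in those comparisons apart from development and the temperatures on day 13. With the block in camera, 6 lists passed for 36.8 °C on day 10 (0 without), 2 on day 13 (6), 3 at day 35 after days 7 to 10 (5) and 7 between temperatures on day 10 (2).

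Signs that changed were as follows. With quantile normalization HSPA8 was 0.027 (36.8 °C, day 10) and -0.0090 (38.8 °C, day 13), and MYOG 0.011 (36.8 °C, day 10). With same-interval controls ATP5J was -0.029. With the block, MYOD1 was 0.031 and MYOG 2.4e-04 (38.8 °C, day 10), RBM3 0.034 and 0.0014 (36.8 °C, days 10 and 13) and CLOCK -0.037; between temperatures at day 35, FGG was 0.79 and 0.94, ALB 0.31 and 0.93, APOB 0.091 and 0.50 (days 7 to 10, days 10 to 13), FGA 1.67, FGB 0.46 and AvBD9 0.17. With the block and W, in the same order without MYOG, the values were 0.029, 0.035, 0.0014, -0.037, 0.78, 0.96, 0.31, 0.93, 0.090, 0.51, 1.67, 0.48 and 0.22. With the block and quantile normalization MYOD1 was 0.027, RBM3 -0.011 and 0.044 (38.8 °C and 36.8 °C, day 10) and HSPA8 0.011; FGG was 0.91 and 0.96, ALB 0.45 and 0.91, APOB 0.0080 and 0.26, FGA 1.74, FGB 0.42 and AvBD9 0.15. With the block and bioB MYOD1 was 0.031, MYOG 2.4e-04, HSPA8 0.013 and RBM3 0.031 and 0.021. The axis difference for 38.8 °C on day 13 was 0.012 with 500 probe sets each way and -0.084 to 0.083 without single treated arrays. The early and late r was 0.012 without dim probe sets for 38.8 °C on days 7 to 10. With own-block controls it was 0.031 there, -0.059 for 36.8 °C on days 7 to 10 and -0.026 for 36.8 °C on days 10 to 13.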

Other observations

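Several gene groups that passed no list test held members that moved between 38.8 °C and 36.8 °C on embryonic day 13. Of 29 cell cycle genes 5 rose and 0 fell over all genes, and 7 rose and 3 fell adjusted over the list alone. Of 19 fast-twitch and common sarcomere genes 3 rose, of 15 slow, cardiac and embryonic sarcomere genes 2 rose, and of 18 myogenic regulation genes 2 rose. With 1 row per gene, 786 of all 11528 genes were called higher in this contrast and 450 lower. Whether these lists hold more called members than that was not tested. On day 10, where 0 members passed over all genes, 10 cell cycle genes were higher, and 9 of 23 heat shock and chaperone genes were higher and 2 lower, by p adjusted over the list alone. Of all probe sets, 24.4 percent had an unadjusted p under 0.05 in that contrast, so such counts are not particular to these lists. The temperatures lie in different listing blocks at both ages. With the block as a term the day 13 medians were -0.12 for cell cycle, -0.03 for fast-twitch sarcomere, -0.10 for slow sarcomere and -0.08 for myogenic regulation genes (camera adjusted p from 0.311 to 0.729), and on day 10 it was -0.07 for cell cycle and 0.03 for heat shock and chaperone genes, of which neither passed.

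The test that sex underlies the chromosome W signal was set before its result was seen. The mean signal of 18 chromosome W probe sets spread over 2 levels at every age, with 11 of 24 arrays above the midpoint on embryonic day 10, 12 of 24 on day 13 and 20 of 40 at day 35. Of the 281 other probe sets associated with it on day 13 and assigned to a chromosome, 95.0 percent lay on chromosome Z, against 4.48 percent of all, and 259 of the 267 on Z were lower where W was high. On day 10 the share was 97.8 percent, and at day 35 it was 77.9 percent. This is consistent with female (ZW) and male (ZZ) birds in the groups.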
